A study of Mus musculus with 18 samples.

How the data were processed

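Gene expression was measured in 18 mouse cell samples, each on 1 Affymetrix Mouse Gene 1.0 ST type array read in a single colour. Total RNA was taken up with a column kit, fragmented and biotin labelled, per the labels' protocols. The deposited values used here are 1 intensity per probe set and array, 28856 probe sets in all. How the authors corrected the background, summarised the probes and scaled the arrays is not given in the sources used here. The values are linear rather than log2, as their range shows: the deposited median intensity per array ran from 142 to 317. Arrays do not share one scale. Identical values, to the last deposited digit, recurred between some arrays: 17.3% of probe sets had the same intensity in the Apc +/+ and Apc Min/Min embryonic stem cell (ESC) arrays, and 9.52 to 19.2% did among derivative #9 and the second pair of embryonic fibroblast arrays. Other pairs of arrays shared at most 0.104%. Such sharing is what quantile normalization of a few arrays at a time leaves behind, so the deposited arrays appear to have been scaled in separate sets.

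Because of this, the log2 intensities of all 18 arrays were quantile normalized together before any comparison. The design written before the data were examined had assumed comparable log2 values, and using the values as deposited was therefore kept as an alternative. Probe sets without values (3) were left out. The platform annotation gave exactly 1 gene symbol for 21789 probe sets, several for 1621 and none for 5443, and those with several or none are not named here. Symbols were checked through Entrez identifiers against the RefSeq gene table of assembly GRCm38.p6, where 21698 of the 21789 matched and 0 symbols changed. The probe set with the highest mean over all arrays stood for a gene, which left 19938 genes. A gene entered a comparison if its value was above the array's median in at least 1 of the arrays compared, the filter being at percentile 50. The number of arrays limits the precision of every value below.

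Groups follow the sample titles: 3 lines of reprogrammed colon tumour cells (RTCs), 2 derivatives of them (#45 from RTC 1 and #9 from RTC 3), 3 ESC lines differing in Apc genotype (Apc +/+, Apc Min/+ and Apc Min/Min), organoids and embryonic fibroblasts (MEFs) derived from #45 with or without 4-hydroxytamoxifen (4-OHT), and S33 ESCs and S33 MEFs with or without doxycycline (dox). The labels give a 4-OHT dose of 1 uM for organoids and 2 ug/ml for MEFs, each for 2 days, and no dose or time for dox. They do not say what was changed in the derivatives, what 4-OHT switches or what S33 stands for. The series text names Apc mutation and induction of mutant beta-catenin in ESCs and MEFs as its subjects.

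Comparisons with replicate arrays were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, two-sided) with Benjamini-Hochberg adjustment at 0.05 over all genes tested. These were RTCs against ESCs (3 RTC lines against Apc +/+, Apc Min/+ and S33 ESCs without dox), RTCs against derivatives (3 against 2), derivatives against the same ESCs (2 against 3) and MEFs with against without 4-OHT (2 against 2). Errors are standard errors from these fits unless given as SD. Whether replicate arrays came from separate cultures is not given in the sources used here, so the p-values may in part measure technical spread. RTC, derivative and ESC arrays enter more than 1 of these comparisons, Apc +/+ and S33 ESCs without dox are also controls of contrasts with 1 array per arm, and no overlap of called genes between comparisons that share arrays is reported. The other contrasts have 1 array per arm and were not tested. For them, genes at least 2-fold apart were counted, and the median of each gene list was placed as a percentile among 10000 random lists of the same size matched on mean level, which describes those arrays only.

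In all, 26 gene lists were written before the data were examined, with 693 names of which 625 were on the array under a single symbol: Wnt target genes, Wnt pathway components, pluripotency, primed pluripotency, trophoblast, primitive endoderm, primitive streak and mesoderm, neuroectoderm, two-cell-stage genes, imprinted genes, intestinal stem cell, enterocyte, Paneth and goblet cell, enteroendocrine cell, fetal and regenerative gut epithelium, fibroblast, immune cell, epithelium, cell cycle, p53 targets, interferon response, senescence-associated secretion, Hox genes, oxidative phosphorylation, glycolysis and sex-linked markers. In tested comparisons each list with at least 5 measured genes was tested with camera, limma's competitive gene set test, with a preset correlation of 0.01 between genes and again with an estimated correlation, and p-values were adjusted over the lists. Some lists share genes. A "call" is an adjusted p under 0.05. Genes were named by a rule also written beforehand: Apc, Ctnnb1, Axin2, Lgr5, Cdx2, Pou5f1 and Nanog wherever measured, the 10 largest rises and 10 largest falls per comparison (among genes past the threshold where there was a test), and up to 4 members of each list with the largest difference, again only those past the threshold where there was a test. Names without a known function behind them were passed over. Genes named outside this rule were chosen after their values were seen, as said where they appear.

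RTC 1 and derivative #45, and RTC 3 and derivative #9, are of the same line of origin by their titles, which pairs them. Their deviations from the group means correlated across genes at 0.09 for the #45 pair and 0.03 for the #9 pair. The fit with the line of origin as a block is given where it changed a call. RTC 2 has no derivative, so it adds nothing to the blocked difference, and this fit leaves 1 residual degree of freedom. The MEF arrays share only the number in their titles. Deviations from the group means correlated at 0.77 across genes between MEF arrays of the same number. With 2 arrays per group this value is the same for both numbers. The arrays numbered 2 are also those with shared intensities, so the fit with this number as a block and the difference within each pair stand beside the unblocked result.

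The fitting steps were tested on simulated data made from the real genes' means and spreads, with 50 genes changed at each of 4 sizes. With spreads as limma moderates them, 43 of 50 genes changed by a log2 of 1 were called in RTCs against ESCs, 27 of 50 in RTCs against derivatives, 32 of 50 in MEFs and 20 of 50 in derivatives against ESCs. With each gene's own spread, these numbers were 32, 8, 18 and 10. Among unchanged genes, between 2 and 15 were called per comparison. The blocked MEF fit called 50 of 50 genes at that size with moderated spreads and 0 of 50 with each gene's own spread, so its calls rest on spreads shared between genes. Simulated lists shifted by a common amount were called in every comparison with the preset correlation, and 0 of 20 unshifted lists were. The simulated genes varied independently of each other, so this cannot show how often camera calls unshifted lists whose genes move together.

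Alternatives were the deposited scale, centring each array on its median, normexp background correction with an offset of 50, no filter or a filter at percentile 70, eBayes with a trend, all 18 arrays in 1 fit, every probe set counted, other fold thresholds, leaving out each array in turn and blocking. Some were chosen after seeing the data, and the closing part says which. The 95% ranges and other settings are given where used. Figures were drawn with matplotlib 3.10.9. Genes whose probe sets carry several symbols or none, T (brachyury) and Ly6a among them, are not analysed here, and no chromosome positions are given.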

Results

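Transcript levels were measured in 18 mouse samples of 4 cell types: pluripotent stem cells, reprogrammed colon tumour cells (RTCs), small intestinal organoids and embryonic fibroblasts (MEFs). RTCs are tumour cells returned to a pluripotent-like state by induced pluripotent stem cell methods. There were 3 RTC arrays, 2 arrays of RTC derivatives (#45 and #9), 1 array each of Apc +/+, Apc Min/+ and Apc Min/Min embryonic stem cells (ESCs), 2 arrays of #45-derived organoids, 4 of #45-derived MEFs, 2 of S33 ESCs and 2 of S33 MEFs. Min is a truncating mutation of Apc, the scaffold that keeps beta-catenin (Ctnnb1) low and so restrains the Wnt pathway. The deposited median intensity per array was 142 to 317, and values below are log2 intensities after all arrays were quantile normalized together. The Apc probe set reads the transcript as a whole, so its level checks neither a point mutation nor the loss of a single exon.

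By whole profile, RTCs sat with the ESCs and apart from intestinal cells and fibroblasts. Across genes, RTC and ESC arrays correlated at 0.961 to 0.981 (9 pairs), RTC and derivative arrays at 0.968 to 0.979 (6 pairs), and RTC arrays among themselves at 0.982 to 0.995. Correlations of RTCs with organoids averaged 0.838 (6 pairs), and those with MEFs were 0.846 to 0.891. The pluripotency factors Pou5f1 and Nanog had mean levels of 13.1 and 13.4 in RTCs, against 12.8 and 13.3 in ESCs. Of the variance between arrays, 49.0% lay on a first axis that set MEFs against all pluripotent cells and 29.2% on a second that set organoids apart. These correlations are across genes, which are not independent replicates. Limited to the 1000 most variable genes, the mean RTC to ESC correlation was 0.892 rather than 0.973.

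**Figure D1:**
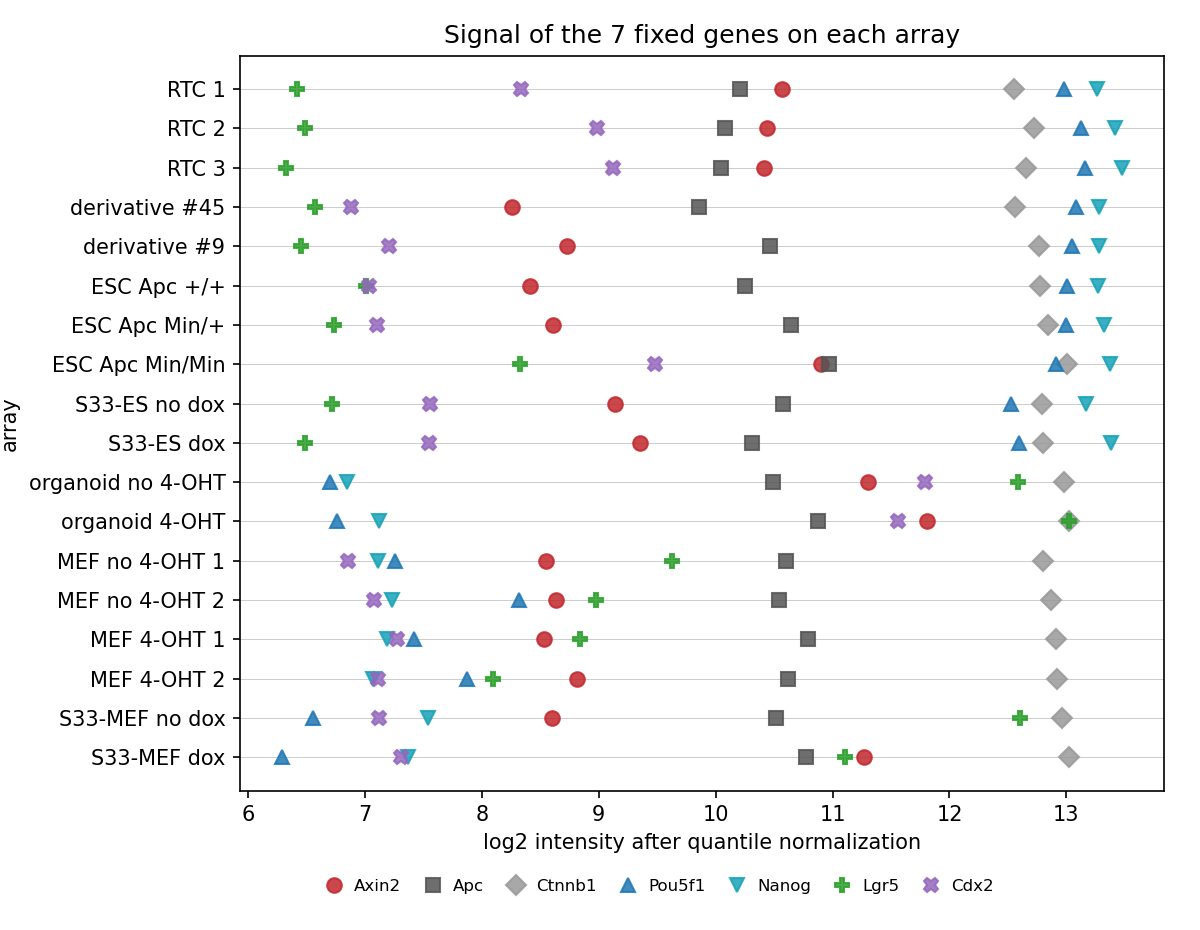
Log2 intensity after quantile normalization (x axis) of 7 genes fixed beforehand on each of the 18 arrays (y axis), with 1 point per gene and array. Axin2 was 10.41 to 10.57 in the 3 RTC arrays and 10.90 in Apc Min/Min ESCs, against 8.26 and 8.72 in derivatives #45 and #9, while Pou5f1 and Nanog were high in all pluripotent cells.

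Whether RTCs share the features of pluripotent stem cells was asked by comparing the 3 RTC lines with 3 ESC arrays (Apc +/+, Apc Min/+ and S33 without dox). RTCs had more of the Wnt feedback gene Axin2 (log2 difference 1.75 ± 0.19, SE, n = 3 and 3, adjusted p = 0.00388). The caudal homeobox gene Cdx1 (1.90 ± 0.26, adjusted p = 0.00783) and the homeobox gene Nkx1-2 (2.96 ± 0.24, adjusted p = 0.0011) were higher too. Cdx2 was at 8.34, 8.98 and 9.12 in RTC 1, 2 and 3, against 7.04, 7.10 and 7.56 in Apc +/+, Apc Min/+ and S33 ESCs. It passed the test, but not in 2 of the 6 fits with an array left out. The largest rises were those of Obox6, an oocyte homeobox gene, by 4.44 ± 0.35 (adjusted p = 0.00109) and the homeobox gene Crxos by 3.68 ± 0.16 (adjusted p = 0.000163). In contrast, the epiblast and anterior neural homeobox gene Otx2 fell by 3.44 ± 0.23 (adjusted p = 0.000575), the Nodal antagonist Lefty1 fell by 3.38 ± 0.40 (adjusted p = 0.00449) and the neuronal filament gene Ina fell by 4.10 ± 0.28 (adjusted p = 0.000575). Pou5f1 differed by 0.24 ± 0.16 (adjusted p = 0.413), Nanog by 0.13 ± 0.12 (adjusted p = 0.562), Apc by -0.38 ± 0.14 (adjusted p = 0.162) and Ctnnb1 by -0.16 ± 0.12 (adjusted p = 0.442). Other large rises were those of Zfy1, a Y-linked zinc finger gene (3.46), Pglyrp1, a bacterial peptidoglycan sensor (3.40), Dmgdh, a mitochondrial enzyme of choline breakdown (3.13), and Lyz2, the lysozyme of myeloid cells (2.87). Further large falls were those of Enpp3 (-3.45), the X-linked homeobox gene Rhox9 (-2.92), the neuronal gene Crmp1 (-2.79), Elmo1 (-2.38), Zic2 (-2.27) and the fatty acid transporter Slc27a2 (-2.25).

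By gene list, 5 of 6 measured two-cell-stage genes rose in RTCs, among them Tdpoz3 (3.15), Tmem92 (3.08), Zfp352 (3.04) and Arg2 (2.23), and 0 fell. The list was called higher by camera (median 2.64, adjusted p = 1.41e-09), with adjusted p = 0.143 with an estimated correlation, and 5 genes were higher when adjusted over the list alone. Of 22 epithelium genes, 9 fell and 0 rose, among them the small GTPase Rab25 (-2.77), the splicing regulator Esrp1 (-2.10), Grhl2 (-1.38) and the protease Prss8 (-1.37). That list was called lower (median -0.79, adjusted p = 4.49e-08), with adjusted p = 0.0756 with an estimated correlation; adjusted over the list alone, 15 genes were lower and 1 higher. All 16 immune cell genes were higher in value and 3 passed the test, Lyz2 (2.87), the adaptor Tyrobp (1.55) and the T cell receptor chain Cd3e (1.47), with 11 higher when adjusted over the list alone. The list's mean level was 8.67 in RTC 2 and 8.69 in RTC 3, but 7.57 in RTC 1 against 7.21 to 7.41 in ESCs. The list was called higher (median 1.26, adjusted p = 4.49e-08), with adjusted p = 0.489 with an estimated correlation. Of 13 primed pluripotency genes, 5 fell and 0 rose, with Zic2 (-2.27), Zic5 (-1.43) and the DNA methyltransferase Dnmt3a (-0.99) beside Otx2, and 7 were lower when adjusted over the list alone. It was called lower (median -0.94, adjusted p = 0.000346), with adjusted p = 0.489 with an estimated correlation.

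Among gut lists, 4 of 9 enterocyte genes rose, including the brush border peptidases Dpp4 (1.47) and Mep1b (1.40), and the list was called higher (median 0.52, adjusted p = 0.00765), with adjusted p = 0.236 with an estimated correlation and 0.0558 (median 0.08) with no filter. Of 8 enteroendocrine cell genes, 4 fell, namely the transcription factors Neurod1 (-1.78), Pax6 (-1.29) and Insm1 (-1.23) and the hormone gene Cck (-1.39), and the list was called lower (median -0.73, adjusted p = 0.0108), with adjusted p = 0.236 with an estimated correlation. In the pluripotency list, 2 of 31 genes rose and 3 fell (median 0.11 but mean -0.06, adjusted p = 0.307): Tbx3 was 1.20 higher, whereas Lefty1, Lefty2 (-2.14) and the maternal factor Dppa3 (-1.46) fell. The Wnt target list was not called (median 0.11, adjusted p = 0.241), although 3 of 23 members rose, Axin2, Cdx1 and Sp5 (1.52), and 0 fell; adjusted over the list alone these were 5 and 1. Without the S33 array that list was called higher (adjusted p = 0.0166), as was the primitive streak and mesoderm list (3 of 16 genes rose, adjusted p = 0.0842 with all arrays and 0.00184 without S33). Called lower without S33 were the trophoblast list (3 rose and 4 fell of 29, median -0.27, adjusted p = 0.248 with all arrays and 0.00771 without S33) and the fetal and regenerative gut list (median -0.42, adjusted p = 0.0321). As deposited, the lists of Wnt targets (0.0195), primitive streak and mesoderm (0.000846), trophoblast (0.0128) and sex-linked markers (0.000846) were called as well. With an estimated correlation and all arrays these 5 lists had adjusted p = 0.743 or more.

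Smaller shifts were called for 7 further lists, each lost when at least 1 array was left out and each at adjusted p = 0.489 or above with an estimated correlation. Of 16 neuroectoderm genes 5 fell and 1 rose (median -0.31, adjusted p = 0.0108; 0.0712 without S33). The fibroblast list had 0 of 24 genes higher in value (median -0.39, adjusted p = 0.0052), and its call was lost without RTC 1 (0.0602), Apc +/+ (0.0666) or Apc Min/+ (0.0762). Its mean level was 10.85 and 10.86 in Apc +/+ and Apc Min/+ ESCs, but 9.75 in S33 ESCs, against 9.71, 10.16 and 10.12 in RTC 1, 2 and 3. The list of senescence-associated secretion (median -0.32, adjusted p = 0.0379) was lost without RTC 1 (0.0966), Apc +/+ (0.211) or Apc Min/+ (0.123). Oxidative phosphorylation (median 0.14, adjusted p = 0.0214) was lost without RTC 3 (0.0526) or S33 (0.052) and as deposited (0.0786). Wnt pathway components (median -0.20, adjusted p = 0.0469), where Tcf7l1 (-1.22) and the receptor Fzd2 (-1.11) fell, were lost without RTC 1 (0.0966), RTC 3 (0.0611), Apc Min/+ (0.101) or S33 (0.188). Primitive endoderm (median 0.11, adjusted p = 0.0469) was lost without RTC 2 (0.381), RTC 3 (0.113), Apc +/+ (0.0519) or S33 (0.396). Interferon response, with 5 of 16 genes higher, Xaf1 (1.88) and Oas1a (1.14) among them (median 0.15, adjusted p = 0.0469), was lost without RTC 2 (0.25) or S33 (0.133) and with no filter (0.274). Uncalled lists were imprinted genes (adjusted p = 0.581, with Plagl1 1.89 higher and Peg3 -1.94), intestinal stem cell (0.284), fetal and regenerative gut epithelium (0.198), cell cycle (0.825), p53 targets (0.431), Hox genes (0.825), glycolysis (0.825, median -0.03 but mean 0.02) and sex-linked markers (0.383), and Paneth and goblet cell had too few measured genes for a test.

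In all, limma called 808 of 12080 genes, 388 higher and 420 lower in RTCs, and 361 of them at least 2-fold. Within the arms, S33 ESCs were 2-fold or more apart from Apc +/+ ESCs in 675 genes, while Apc Min/+ and Apc +/+ were in 12. RTC 1 was so from RTC 2 in 391 and from RTC 3 in 322, while RTC 2 and RTC 3 were in 22. The number of genes called changed when an array was left out. It was 234 without RTC 3, 281 without RTC 2, 282 without Apc Min/+, 344 without Apc +/+, 664 without RTC 1 and 1170 without S33. Each such fit also has fewer arrays from which to estimate the spread. That holds whichever array is left out, while the lowest counts came without an array of a close pair, RTC 2 and RTC 3 or Apc Min/+ and Apc +/+. Of 68 named genes past the threshold, 37 stayed past it whichever array was left out, Axin2, Cdx1, Nkx1-2, Obox6, Crxos, Otx2, Lefty1, Ina and Rab25 among them. The other 31 were lost without at least 1 array. The adjusted p without RTC 3 was 0.0551 for Zic2, 0.121 for Zic5, 0.124 for Dnmt3a, 0.0953 for Slc27a2 and Neurod1, 0.0733 for Sp5, 0.0917 for Cck, 0.152 for Mep1b, 0.121 for Fzd2, 0.126 for Oas1a and 0.105 for Peg3. Without Apc Min/+ it was 0.111 for Lyz2, 0.143 for Tyrobp, 0.107 for Rhox9, 0.0552 for Dppa3 and 0.0785 for Tcf7l1, and without RTC 2 it was 0.0645 for Lefty2. As deposited, the count was 358 with 213 higher and 145 lower, and with arrays centred on their median 710 with 437 higher and 273 lower; without the S33 array and X- and Y-linked genes it was 1098 with 436 higher and 662 lower.

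RTC derivatives were compared with RTCs under the series' question of what Apc mutation does in different cells. As background not stated in the labels, the derivatives are taken to be RTCs in which Apc function was restored. RTCs had more Axin2 than derivatives (1.98 ± 0.20, SE, n = 3 and 2, adjusted p = 0.00737), more Sp5, a Wnt-induced transcription factor (1.69 ± 0.17, adjusted p = 0.00737), more Cdx1 (1.5 ± 0.19, adjusted p = 0.0189) and more Nkx1-2 (2.59 ± 0.21, adjusted p = 0.00332). Lefty1 fell by 4.06 ± 0.22 (adjusted p = 0.00105), the neurogenic factor Neurod1 fell by 3.11 ± 0.22 (adjusted p = 0.00233) and Zic2 fell by 2.77 ± 0.18 (adjusted p = 0.00216) in RTCs relative to derivatives. Pou5f1 (0.02 ± 0.17, adjusted p = 0.973), Nanog (0.11 ± 0.17, adjusted p = 0.848), Ctnnb1 (-0.02 ± 0.18, adjusted p = 0.976) and Apc (-0.06 ± 0.22, adjusted p = 0.945) did not pass the test. The largest rises further included Pglyrp1 (3.79), Dmgdh (3.15), Crxos (2.72), the transcriptional coregulator Cited1 (2.46), Bhmt2 (2.45), Cd3g (2.30), the transporter Flvcr2 (2.30), Xaf1 (2.29) and the imprinted gene Plagl1 (2.20), and the largest falls Enpp3 (-3.42), Ina (-3.16), Crmp1 (-3.03), Otx2 (-2.99), Elmo1 (-2.56), Map7d3 (-2.41) and Usp26 (-2.15).

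Of 24 Wnt target genes, 5 rose and 0 fell: Axin2, Sp5, Cdx1, the receptor ligase Rnf43 (1.09) and the transcription factor Lef1 (1.05). The list was called higher (median 0.22, adjusted p = 0.000591), with adjusted p = 0.616 with an estimated correlation and 0.0738 without derivative #45, and 6 genes were higher and 1 lower when adjusted over the list alone. With the line of origin as a block, Rnf43 (adjusted p = 0.0718) and Lef1 (adjusted p = 0.0882) were no longer called. Primitive streak and mesoderm genes rose in 4 of 11 cases, with the signalling gene Bmp4 (1.77) beside Nkx1-2, Sp5 and Cdx1, and 0 fell (median 0.72, adjusted p = 2.83e-05; 5 higher when adjusted over the list alone), with adjusted p = 0.515 with an estimated correlation. With no filter on dim genes the median of that list was -0.00, although it was still called higher. Of 7 two-cell-stage genes, 3 rose, Tmem92 (2.00), Zfp352 (1.93) and Arg2 (1.47), and 5 did when adjusted over the list alone (median 1.44, adjusted p = 4.92e-06), with adjusted p = 0.515 with an estimated correlation.

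Of 16 neuroectoderm genes 5 fell, including the eye and forebrain gene Pax6 (-2.07) beside Neurod1, Otx2 and Zic2, and 0 rose (median -0.18, adjusted p = 0.000685), with adjusted p = 0.515 with an estimated correlation. Of 12 primed pluripotency genes 3 fell, Otx2, Zic2 and Zic5 (-2.09), and 1 rose, Lef1 (median -0.53, adjusted p = 0.000591), with adjusted p = 0.515 with an estimated correlation. Enteroendocrine cell genes fell in 3 of 8 cases, Neurod1, Pax6 and Insm1 (-1.39), with a list median of -0.58 (adjusted p = 0.00015) and adjusted p = 0.515 with an estimated correlation. In the epithelium list, Elf3 rose (1.46) and Esrp1 fell (-1.20) of 22 genes, with 8 lower and 2 higher when adjusted over the list alone; it was called lower (median -0.42, adjusted p = 0.0125; 0.166 without derivative #45), with adjusted p = 0.515 with an estimated correlation. Immune cell genes had 0 of 16 past the test but 15 higher in value (median 0.70, adjusted p = 0.000863; 0.116 without derivative #9), with adjusted p = 0.626 with an estimated correlation; within the #45 pair the list's mean level was lower in RTC 1 (7.57) than in the derivative (7.91).

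Another 6 lists were called higher without the block and not with it. These were primitive endoderm (median 0.50, adjusted p = 0.00585; 0.1 blocked), trophoblast (0.32, adjusted p = 0.0249; 0.0518 blocked), interferon response (0.22, adjusted p = 0.0249; 0.0547 blocked), intestinal stem cell (0.18, adjusted p = 0.0288; 0.0978 blocked, with a median of -0.01), fibroblast (0.23, adjusted p = 0.0315; 0.157 blocked) and glycolysis (0.14, adjusted p = 0.0315; 0.0547 blocked, with a median of -0.01 when arrays were centred on their median). With an estimated correlation each had an adjusted p of 0.616 or more. In the trophoblast list, Bmp4, Cdx2 (1.77 ± 0.27) and Gata2 (1.23) rose and the receptor Fgfr2 (-1.5) fell. Among lists that were not called, pluripotency had 1 gene lower and 0 higher of 31 (median 0.11 but mean -0.05, adjusted p = 0.252), and p53 targets 1 lower of 23 (Plk3, -1.87). Sex-linked markers were not called (adjusted p = 0.139) but were as deposited (0.0167) and without RTC 3 (0.00325), with adjusted p = 0.626 with an estimated correlation and all arrays.

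limma called 191 of 11940 genes, 100 higher and 91 lower in RTCs. The fit with the line of origin as a block called 232, of which 142 were shared. Its differences come from RTC 1 and RTC 3 with their derivatives only, on 1 residual degree of freedom. The unblocked count too changed when an RTC array was left out. It was 33 without RTC 1, 37 without RTC 3 and 56 without RTC 2, again with fewer arrays to estimate the spread. Of 39 named genes past the threshold, 15 stayed past it whichever array was left out, Nkx1-2, Sp5, Lefty1, Neurod1 and Zic2 among them, while Axin2 had adjusted p = 0.0633 without RTC 1. Also lost without RTC 1 were Otx2 (0.13), Pax6 (0.0974), Pglyrp1 (0.0611), Xaf1 (0.0709), Plagl1 (0.0829), Map7d3 (0.0527), Cd3g (0.0653), Flvcr2 (0.0969), Tmem92 (0.0709), Zfp352 (0.0914), Plk3 (0.1) and Fgfr2 (0.098). Lost without RTC 3 were Cdx1 (0.0885), Cdx2 (0.097), Bmp4 (0.104), Arg2 (0.135), Elf3 (0.116), Esrp1 (0.161), Gata2 (0.129), Insm1 (0.13), Lef1 (0.202) and Rnf43 (0.15). As deposited, 81 genes were called, 58 higher and 23 lower; centred on the median there were 173, 100 higher and 73 lower.

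Against the same 3 ESC arrays, derivatives had Axin2 at -0.23 ± 0.27 (SE, n = 2 and 3, adjusted p = 0.847), Apc at -0.33 (adjusted p = 0.737), Pou5f1 at 0.22 (adjusted p = 0.800) and Nanog at 0.02 (adjusted p = 0.976). limma called 0 of 11941 genes, and 1012 had an unadjusted p under 0.05 where 597 would by chance. The 2 derivatives were 2-fold or more apart in 730 genes, and the self-test called 20 of 50 simulated genes changed by a log2 of 1. As deposited, 11 genes were called, and with all 18 arrays in the fit 106. Among lists, camera called fibroblast lower, with 0 of 24 genes higher in value (median -0.68, adjusted p = 2.17e-07), trophoblast lower (median -0.46, adjusted p = 3.1e-07) and immune cell higher, with 10 of 10 genes higher in value (median 0.72, adjusted p = 0.000117). With an estimated correlation these had adjusted p = 0.641, 0.476 and 0.476. The fibroblast list's mean level was 10.85 in Apc +/+ and 10.86 in Apc Min/+ ESCs, but 9.75 in S33 ESCs. It was 9.96 in derivative #45 and 9.59 in derivative #9, so the S33 array lay between them. Epithelium (median -0.35, adjusted p = 3.1e-05) and senescence-associated secretion (median -0.42, adjusted p = 0.00413) were called lower and lost without derivative #9 (0.0686 and 0.28), with adjusted p = 0.476 and 0.641 with an estimated correlation. The other 5 called lists were each lost under at least 2 settings and had adjusted p = 0.476 or more with an estimated correlation: p53 targets higher (median 0.17, adjusted p = 0.0114; 0.444 without derivative #9), Wnt pathway components lower (-0.20, adjusted p = 0.0228; 0.823 without derivative #45), fetal and regenerative gut lower (-0.24, adjusted p = 0.03; 0.277 without #9), enterocyte higher (0.39, adjusted p = 0.0366; 0.105 with no filter) and glycolysis lower (-0.15, adjusted p = 0.0366; 0.863 as deposited). Oxidative phosphorylation was not called (adjusted p = 0.0581) but was under 4 settings, as deposited (0.000556) among them, with adjusted p = 0.731 with an estimated correlation and all arrays. The Wnt target list was not called (median -0.17, adjusted p = 0.0581), but it was called lower as deposited (0.0392), with arrays centred on their median (0.0349), with no filter (0.0454) and without Apc Min/+ (0.0128), Apc +/+ (0.0135) or derivative #9 (0.0242), and not without derivative #45 or S33, with adjusted p = 0.724 with an estimated correlation and all arrays.

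ESCs homozygous for Min were set against Apc +/+ ESCs, 1 array each, so this contrast and the organoid, S33 ESC and S33 MEF contrasts have no replicates and no test. Apc Min/Min ESCs had 2.49 more Axin2 (log2) than Apc +/+ ESCs, 3.48 more of the secreted Wnt antagonist Dkk1 and 1.31 more of the R-spondin receptor Lgr5, with Apc 0.71 and Ctnnb1 0.23 higher. Extraembryonic endoderm regulators were far higher: Sox17 by 4.23, Gata4 by 3.53 and Gata6 by 3.47. Otx2 was at -3.11, Ina at -3.48, Lefty1 at -2.76 and Rab25 at -2.73, while Pou5f1 (-0.09) and Nanog (0.11) lay close to the control. Of the largest differences, Kcnma1, a potassium channel, was 5.36 higher, the peptidase Enpep 4.11, Nr4a3 4.05, Pramel19 3.79, Hs3st1 3.47 and the water channel Aqp8 3.43. At the other end stood Pipox (-3.39), Enpp3 (-3.27), Hsd17b14 (-2.97), Crmp1 (-2.89) and Col10a1 (-2.85).

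By list, 16 of 20 primitive endoderm genes were at least 2-fold higher and 0 lower (median 1.65), among them the receptor Cubn (2.91). Wnt target genes had 9 of 24 at least 2-fold higher, Sox9 (1.79) among them, and 1 lower, Ascl2 (-2.08), with a median of 0.71. Primitive streak and mesoderm genes had 5 of 9 higher and 0 lower (median 1.36), with Nkx1-2 at 3.40 and the receptor Flt1 at 2.28. Two-cell-stage genes had 5 of 6 higher (median 2.26), with Tdpoz3 at 2.85 and Tmem92 at 2.68. Each of these medians was at percentile 100 among 10000 random lists. Primed pluripotency genes had 7 of 11 lower and 0 higher (median -1.38, percentile 0), with Zic5 at -1.93 and Cldn6 at -1.80, and neuroectoderm 6 of 14 lower (median -0.74, percentile 0.03). Epithelium genes had 9 of 22 lower and 1 higher (median -0.51, percentile 0.03), with Prss8 at -2.49 and Cldn4 at -2.36. Imprinted genes moved both ways, with 5 of 19 higher and 3 lower: Plagl1 was at 3.00 and Airn at 2.56 against Phlda2 at -2.71. Cdx2 was 2.45 higher, yet Gata3 (-2.45) and Rhox9 (-2.65) of the trophoblast list were lower, and that list had 3 of 28 higher and 6 lower (median -0.15, percentile 20.2). Immune cell genes had 3 of 5 higher, with Lyz2 at 2.83 (median 1.01, percentile 99.8).

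In total 1168 of 11390 genes were at least 2-fold apart, 524 higher and 644 lower, whereas Apc Min/+ and Apc +/+ ESCs differed in 12 genes, 8 higher and 4 lower, with Axin2 0.20 higher in Apc Min/+. All lists had 0 genes at least 2-fold apart in that second contrast. Beyond both other arrays in the same direction by 2-fold lay 434 genes that were higher and 526 that were lower in Apc Min/Min. The direction split depended on scaling, with 449 higher and 848 lower as deposited, where the median over all genes was -0.15, and 642 higher and 526 lower when centred on the median. A medium for trophoblast stem cells is named for Min/Min ESCs in the labels' growth protocol, so medium and genotype may not be separable here.

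**Figure D2:**
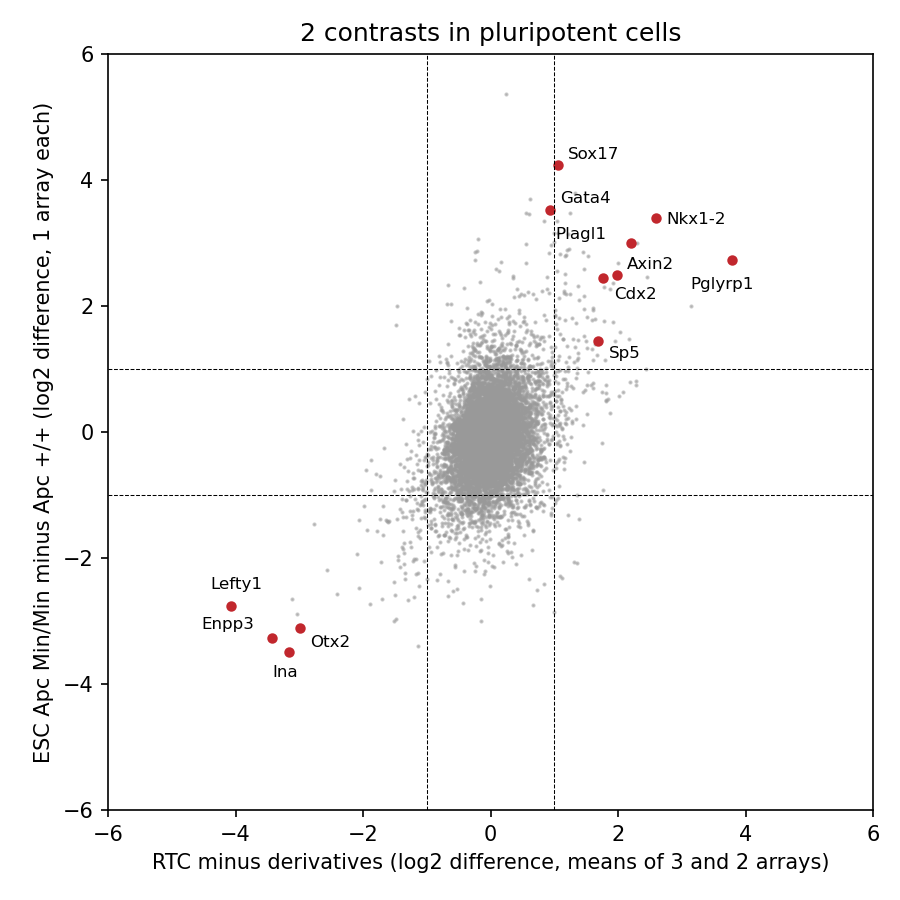
Log2 difference of RTCs minus derivatives (x axis, means of 3 and 2 arrays) against Apc Min/Min minus Apc +/+ ESCs (y axis, 1 array each) for 11099 genes measured in both, 1 point per gene, with dashed lines at 2-fold. Axin2, Cdx2, Sp5, Nkx1-2, Plagl1 and Pglyrp1 were higher and Lefty1, Enpp3, Ina and Otx2 lower in both contrasts, while Gata4 was 3.53 higher in Apc Min/Min ESCs.

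Organoids from #45 were compared with and without 4-OHT, 1 array each; 4-OHT is the usual switch of Cre-ER fusion proteins, and here is taken to remove Apc function, which the labels do not state. With 4-OHT, genes of fetal and regenerating gut were higher: Anxa1 by 4.02, the chaperone Clu by 2.40, Msln by 1.92 and the keratin Krt4 by 1.91. The Wnt targets Prox1 (2.71), Nkd1 (2.08), Tnfrsf19 (1.89) and Sfrp5 (1.46) were higher as well, with Axin2 at 0.50 and Lgr5 at 0.44 from levels of 11.30 and 12.59 without 4-OHT. Apc was at 0.38, Ctnnb1 at 0.04 and the intestinal homeobox gene Cdx2 at -0.23. The largest differences further included Ifitm1 (4.62), the oxidase Nox1 (3.55), Ly6g (3.15), Bex1 (3.13), fibronectin Fn1 (3.07), Sbspon (2.78), Tuba1a (2.66) and Tut4 (2.65). Xist, the RNA that silences the second X chromosome, was lower by the largest amount (-5.03), with the Y-linked genes Uty and Eif2s3y 1.10 and 0.81 higher. Other low values were those of the Paneth cell genes Ang5 (-2.70) and Mptx1 (-2.19), the neuritin Nrn1 (-2.44), and the metabolic genes Adh4 (-2.06), Cyp2c70 (-2.01), Sult1c2 (-1.96), Aldh1l2 (-1.93) and Ces1f (-1.91).

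Of 13 genes of the fetal and regenerative gut list, 9 were at least 2-fold higher and 0 lower (median 1.33, percentile 100). Wnt target genes had 7 of 25 at least 2-fold higher and 24 higher in value (median 0.55, percentile 100), and intestinal stem cell genes 2 of 24 at least 2-fold higher and 21 higher in value (median 0.40, percentile 100). Cell cycle genes were higher in 27 of 33 cases by small amounts (median 0.20, percentile 100), with Kif20a at -1.29. Enterocyte genes had 1 of 29 at least 2-fold higher and 0 lower (median -0.18, percentile 0.05). Paneth and goblet cell genes had 2 of 21 higher, Mmp7 (1.23) and Pla2g2a (1.07), and 2 lower, Mptx1 and the goblet cell lectin Zg16 (-1.63), with a median of -0.15 at percentile 1.19. Oxidative phosphorylation stood at -0.20 (percentile 0). Fibroblast genes had a median of -0.43 (percentile 0.23) even though Fn1 and Vim (1.53) were higher, and immune cell genes one of -0.07 (percentile 38.1).

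Counting genes at least 2-fold apart gave 324 of 11397, 239 higher and 85 lower, but the split turned with scaling: 104 higher and 622 lower as deposited, where the median of all genes was -0.22, and 155 higher and 257 lower when centred on the median. The lists given here kept their sign under each scaling. Without X- and Y-linked genes the count was 308, and because the sex-linked genes differ, the organoid arrays may differ in more than 4-OHT.

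MEFs from #45 were compared with and without 4-OHT, 2 arrays each. Axin2 differed by 0.08 ± 0.13 (SE, n = 2 and 2, adjusted p = 1), Apc by 0.13 and Lgr5 by -0.84 ± 0.36 (both adjusted p = 1), and Wnt target genes had a median of 0.03 over 21 genes (adjusted p = 0.572), while their mean was -0.06 and the median turned to -0.03 as deposited. limma called 0 of 11603 genes, and 519 had an unadjusted p under 0.05 where 580 would by chance. The arrays differed more by their number in the titles than by 4-OHT: 387 genes were 2-fold or more apart between the 2 arrays without 4-OHT and 324 between those with it, and the myeloid gene Lyz2 stood at 13.20 and 13.26 in the first pair against 10.50 and 10.22 in the second. Camera called fibroblast genes lower (25 genes, median -0.33, adjusted p = 1.63e-10), glycolysis higher (19 genes, median 0.14, adjusted p = 3.23e-05), primitive endoderm lower (16 genes, median -0.20, adjusted p = 0.000906; 0.0582 with no filter) and Wnt pathway components lower (29 genes, median -0.11, adjusted p = 0.00218; 0.139 without the second array without 4-OHT). With an estimated correlation each of the 4 had adjusted p = 0.375, and adjusted over the list alone 4 fibroblast genes were lower and 1 glycolysis gene higher. Further lists were called when 1 array was left out, but not in a steady direction: cell cycle had a median of 0.17 without the first array with 4-OHT and -0.32 without the second.

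With the title number as a block, which leaves 1 residual degree of freedom, limma called 148 genes, 54 higher and 94 lower with 4-OHT. Genes of sterol synthesis and its control were among the largest rises, each higher in both pairs: Lss by 1.99 and 1.34 (adjusted p = 0.0345), Idi1 by 1.92 and 1.37 (adjusted p = 0.0303), Tm7sf2 by 1.57 and 1.06 (adjusted p = 0.0376), Insig1 by 1.43 and 1.06 (adjusted p = 0.0303), with Hsd17b7, Stard4 and Cyp51 between 0.83 and 1.40. The inositol transporter Slc5a3 (1.38), Crct1 (1.35) and the glycolytic enzyme Aldoc (1.29) rose too. The largest falls were those of Cxcl13 (-1.32), the imprinted gene Mest (-1.31), the Wnt antagonist Sfrp4 (-1.24), Tnmd (-1.19), Lum (-1.17), elastin Eln (-1.16), Igfbp3 (-1.14), Egfl6 (-1.07), Serpina3n (-1.06) and Igfbp5 (-1.05). Lgr5 was called lower (-0.84, adjusted p = 0.0328), and Axin2 was at -0.02 and 0.18 in the pairs (adjusted p = 0.674). The pairs' differences correlated at 0.516 across genes, and 15 genes were 2-fold or more apart the same way in both, of 56 in the first and 45 in the second. Under the block the same 4 lists were called, and imprinted genes (median -0.15, adjusted p = 0.00055) and immune cell (median -0.38, adjusted p = 1.49e-05) were called lower in addition, each with adjusted p = 0.712 with an estimated correlation.

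The effect of inducing mutant beta-catenin, as the series text names it, was addressed with dox in S33 ESCs and S33 MEFs, 1 array per arm. In S33 MEFs dox went with 2.67 more Axin2, 3.29 more of the Wnt deacylase Notum, 3.17 more Nkd2, 2.95 more of the BMP and Wnt inhibitor Apcdd1 and 2.47 more Lef1 and Rnf43 each, with Ctnnb1 at 0.06. Lgr5 was lower with dox (11.11 against 12.60 without). The mesendoderm factor Eomes (3.22), the chemokine receptor Cxcr6 (4.25), the desmosome gene Dsp (3.13) and the neuropeptide gene Tac1 (3.03) were higher, as were Dynap (4.71), Lce1h (4.41), Cadps (4.39), Tnfsf9 (3.95), Mcpt8 (3.68), Sstr2 (3.32) and Car2 (3.22). Cell cycle genes were lower, among them the checkpoint kinase Bub1b (-2.05) and topoisomerase Top2a (-1.87). Further low values were those of the tight junction gene Cldn1 (-4.12), Egfl6 (-3.78), Ldb2 (-3.22), Ptn (-3.20), Enpp3 (-3.13), Nrk (-3.01), Cxcl5 (-2.96), Medag (-2.90), Idi1 (-2.75) and Srpx (-2.63).

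In S33 MEFs, 11 of 23 Wnt target genes were at least 2-fold higher with dox and 2 lower (median 0.68, percentile 100), the lower ones including Lgr5. Cell cycle genes had 21 of 33 at least 2-fold lower and 0 higher (median -1.29, percentile 0), and interferon response genes 7 of 16 lower and 0 higher, with Ifit1 at -1.84 and Stat2 at -1.54 (median -0.85, percentile 0). Imprinted genes had 7 of 18 lower and 0 higher, with Mest at -2.11, Peg3 at -1.99 and Plagl1 at -1.86 (median -0.68, percentile 0). Hox genes were higher in value in 25 of 30 cases (median 0.42, percentile 100). Senescence-associated secretion went both ways, with 5 of 21 higher, the proteases Mmp10 (2.50) and Mmp3 (2.30) among them, and 4 lower. Fibroblast genes had 3 of 25 lower, Lum (-2.32), Dcn (-1.97) and Eln (-1.68), at a median of 0.04 and a mean of -0.21. In total 708 of 11390 genes were at least 2-fold apart, 285 higher and 423 lower.

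In S33 ESCs dox went with little difference in Axin2 (0.22) or Ctnnb1 (0.01), while Lef1 was at -2.59, the cyclin Ccnd2 at -2.15 and the surface receptor Cd44 at -1.86. Pou5f1 (0.07) and Nanog (0.21) were close to the array without dox. Cubn (2.59), Gata6 (2.07) and Srgn (1.92) were higher, as were the germ cell genes Dazl (2.16) and Sohlh2 (2.27), Igsf21 (2.89), Slc44a3 (2.28), Pde8a (2.18), Neurod1 (1.99) and Ankrd44 (1.90). Among the largest falls were those of Tagln (-2.89), Acta2 (-2.58), Lox (-2.56), Actg2 (-2.40), Fndc3c1 (-3.45), Sema6a (-2.79), Shisa6 (-2.75), Meis2 (-2.54) and the kinase Pim2 (-2.50). Of 21 fibroblast genes 9 were at least 2-fold lower and 0 higher in value (median -0.82, percentile 0). Primed pluripotency genes had 5 of 13 lower and 0 higher, with Fgf5 at -1.51 and Dnmt3b at -1.48 (median -0.92, percentile 0). Senescence-associated secretion (6 of 13 lower, median -0.71) and imprinted genes (2 of 16 lower, median -0.53) were at percentile 0 too, and Wnt target genes (4 of 22 lower and 0 higher, median -0.28) at percentile 0.01. Primitive endoderm had 5 of 18 higher and 1 lower (median 0.27, percentile 99.9). Dox thus came with 356 of 11254 genes at least 2-fold apart, 111 higher and 245 lower; without genes 4-fold or more higher in MEFs than in derivatives the count was 231, 110 higher and 121 lower.

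**Figure D3:**
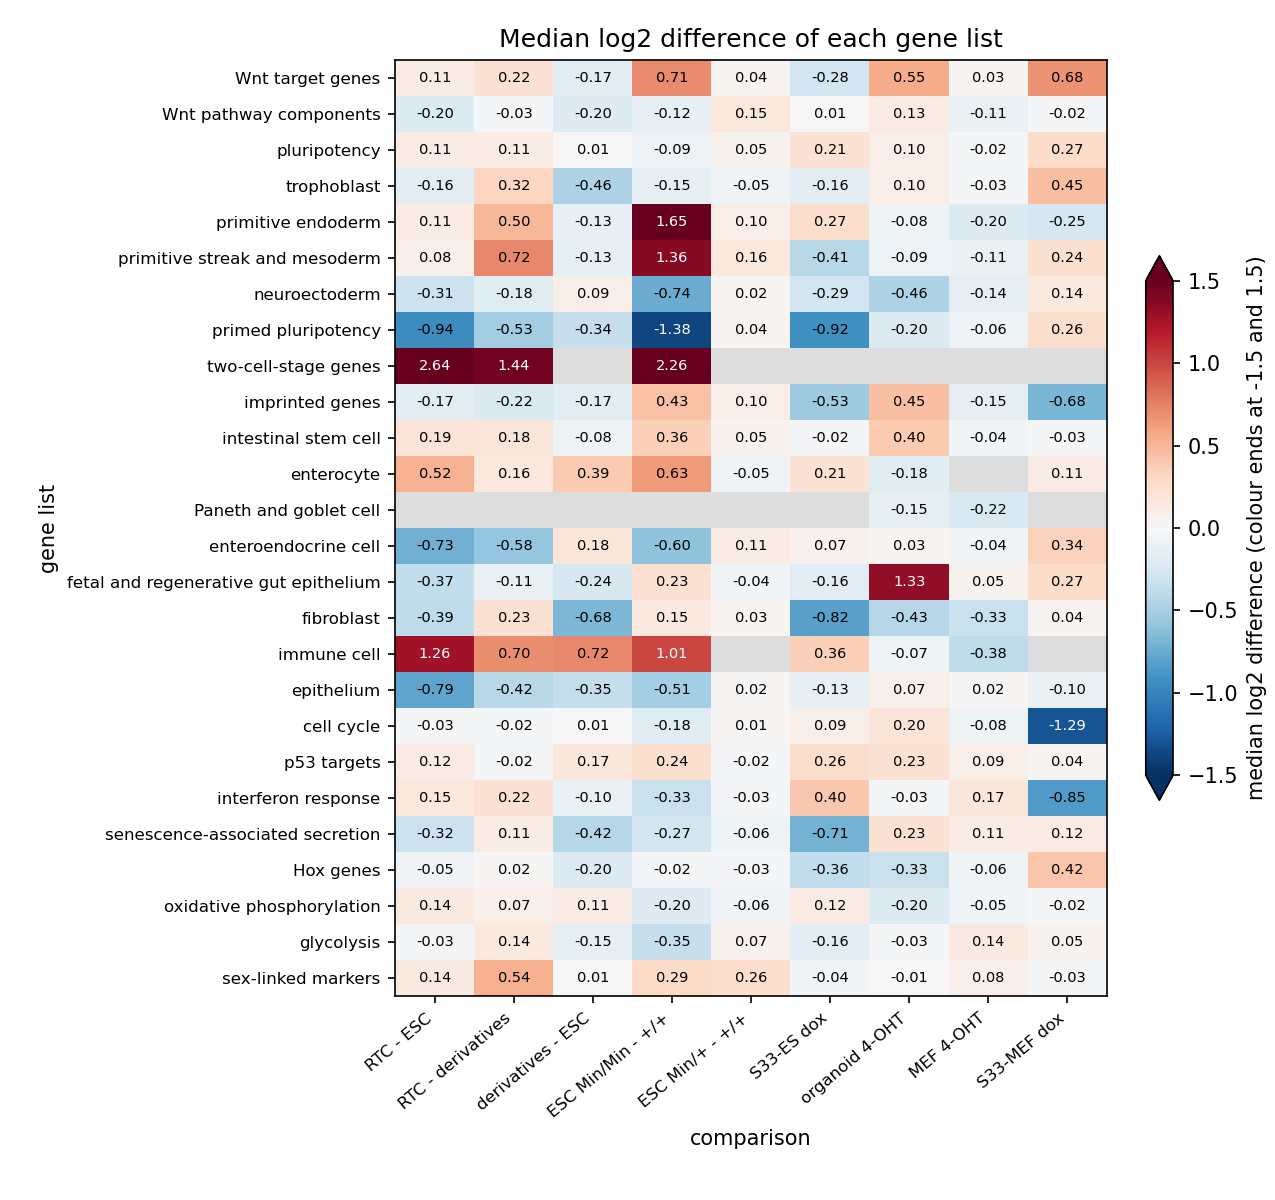
Median log2 difference of each of the 26 gene lists (rows) in 9 contrasts (columns), with the median printed in each cell and grey where fewer than 5 genes were measured. Wnt target genes stood at 0.71 in Apc Min/Min ESCs, 0.55 in organoids with 4-OHT and 0.68 in S33 MEFs with dox, against -0.28 in S33 ESCs with dox and 0.03 in MEFs with 4-OHT.

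How far the response depends on the cell type was described by setting 6 contrasts side by side over 13930 genes: RTCs minus derivatives, Apc Min/Min minus Apc +/+ ESCs, 4-OHT in organoids and MEFs, and dox in S33 ESCs and S33 MEFs. No array enters more than 1 of them. RTCs minus derivatives and Apc Min/Min minus Apc +/+ ESCs were the most alike (r = 0.34, Spearman's rho = 0.23 across genes). They shared 91 genes at least 2-fold higher, where independent lists would share 9.03, and 94 lower, where 9.38 would be shared. Axin2, Cdx1, Cdx2, Sp5, Nkx1-2, Plagl1 and Sox17 were among the first, and Otx2, Lefty1, Neurod1, Zic2, Ina and Rab25 among the second. Without derivative #45 this r was 0.14. For dox in S33 ESCs r was 0.14 with RTCs minus derivatives and 0.13 with Apc Min/Min ESCs. Every other pair, those of 4-OHT in organoids or MEFs and dox in S33 MEFs included, lay between -0.06 and 0.08, but the order of pairs depended on scaling: as deposited or with arrays centred on their median, 4-OHT in organoids and in MEFs had r = 0.15, above the 2 pairs of S33 ESCs (0.12 and 0.11). At least 2-fold higher in 4 of the 6 were Cubn, Glipr1 and the Wnt target Tnfrsf19, and at least 2-fold lower in 4 were Dppa3 and Mest, while 0 genes moved so in 5 or 6. Genes are not independent replicates, and the dose, time and medium of these contrasts differ.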

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

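Of the tests in this part, those of X-linked genes, of sterol synthesis genes in organoids and of other splits of the arrays were chosen before their result was seen, and the others after.

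With dox, 4 of the named genes moved 2-fold or more in opposite directions in S33 ESCs and S33 MEFs: the Wnt effector Lef1 was at -2.59 in ESCs and 2.47 in MEFs, Gata6 at 2.07 and -1.03, Ankrd1 at -1.94 and 1.23, and Fabp7 at -2.09 and 1.31. With 1 array per arm, the difference between the cell types was not tested. For Lef1, Ankrd1 and Fabp7, the level in at least 1 kind of untreated MEFs was not below that left in the ESC dox array. Fewer feeder fibroblasts, taken up below, may therefore explain their falls in ESCs. Among probe sets without a single gene symbol, which no comparison of the report uses, 115 of 2863 passed the threshold in RTCs against ESCs and 1 of 2853 in RTCs against derivatives.

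In organoids with 4-OHT, Xist was at -5.03 while the Y-linked genes Uty, Eif2s3y and Kdm5d were at 1.10, 0.81 and 0.73. The rise of Kdm5d depended on scaling: it was at -0.15 as deposited and 0.04 when arrays were centred on their median. Against an effect of 4-OHT on Xist in any cell type stands its mean difference of 0.14 in the 2 MEF pairs. Against reactivation of a silent X chromosome, 290 X-linked genes moved by a median of 0.0565 more than genes on other chromosomes (95% bootstrap range 0.02 to 0.12), where 0.3 or more had been required. That the 2 arrays hold cells of different sex in different shares may explain the pattern and stays open: the lowest of 12 differences of the 3 Y-linked genes under 4 scalings, relative to all genes, was 0.0766, but this repeats the pattern on its own genes, with 2 of the scalings identical, and decides nothing. Escape genes such as Kdm6a (0.12) and Kdm5c (-0.16) went both ways and do not settle it. In the derivative line of the organoids, Eif2s3y was at 10.49, against 8.81 without and 9.62 with 4-OHT. Uty was at 9.63 (7.66 and 8.76), Kdm5d at 7.35 (6.67 and 7.40) and Xist at 7.69 (10.52 and 5.49). All 3 Y-linked genes were higher in that line than in the array without 4-OHT, but levels can differ between cell types. That array may hold cells from outside the line, which was not tested.

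In S33 ESCs with dox, fibroblast genes were lower, with Col1a1 going from 10.01 to 9.03, Tagln from 11.32 to 8.43 and Lox from 10.81 to 8.25. Fewer feeder fibroblasts, which the labels do not mention, may explain 1 part. Genes 4-fold or more higher in MEFs than in derivatives made up 50.6% of the 245 lower genes against 4.28% of all genes tested. That share repeats the fall of fibroblast genes, so it gives the size of this part and does not test for feeders. For 18.4% of the lower genes (45 genes, among them Fndc3c1, Pim2, Lefty1 and Dnmt3b) the level in untreated MEFs was below that left in the dox array. A loss of feeders alone could not lower these genes if feeders express them as these MEFs do, which was not measured. The 45 genes were not kept apart from those 4-fold higher in MEFs. A rise of Wnt signalling with dox was not seen in the Wnt target list, whose median was -0.28. Its members at least 2-fold lower, Lef1, Ccnd2, Cd44 and Myc, were not among the 45 genes. A loss of feeders may have lowered them, so this median need not reflect the ESCs alone. What dox changed in the ESCs themselves stays open with 1 array per arm.

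In MEFs with 4-OHT, 20 of 20 sterol synthesis genes were higher in both pairs, with medians of 1.24 and 0.70, so neither pair alone carries the rise. The list was written after Lss, Idi1 and Insig1 had been seen, limma called 13 of its genes with the block and 0 without it, and its camera p was 2.6e-28 with the preset correlation and 0.0963 with an estimated one. In organoids with 1 uM 4-OHT the rise was not seen, as the list's median was -0.23 with 1 array per arm. This argues against an effect in any cell type at that dose. MEFs had 2 ug/ml, so organoids cannot decide whether the MEF dose would raise the list in any cell type. As a biological explanation, activation of Wnt signalling was set against S33 MEFs with dox. There the list's median was -1.29, and 16 of 20 genes were at least 2-fold lower. Cell cycle genes fell on the same arrays, from a mean level of 10.48 to 9.31. With 1 array per arm and another treatment, that contrast cannot decide whether Wnt signalling raised the list in MEFs with 4-OHT. In those MEFs the Wnt target list was not called (median 0.03 of 21 genes), and this explanation stays open. An effect of 4-OHT on fibroblasts alone, at a dose that differed from that of organoids, may be the source and was not tested.

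For RTCs against ESCs, 1 of the 10 splits of the 6 arrays into 3 and 3 gave 808 or more genes, the real one, and the highest of the others gave 0. With 10 splits a share under 0.05 cannot be reached.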

How the results depend on the processing

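Normexp correction, the use of Apc Min/+ as the sole ESC array, removal of X- and Y-linked or fibroblast-high genes, blocks for gene lists, left-out arrays for lists and for the shared response, and centring for the shared response were chosen after seeing the data; the other settings were fixed before. No named gene that was called or at least 2-fold apart reversed its direction under any setting, but the split of counts into higher and lower turned for organoids (as deposited and centred), for Apc Min/Min ESCs (centred, and at a fold of 3), and under several settings for RTCs against ESCs and against derivatives. Of called lists, the median changed sign for glycolysis when arrays were centred on their median (-0.01 in RTCs against derivatives, where it was -0.02 without derivative #9, and 0.10 in derivatives against ESCs). In RTCs against derivatives it also did so for intestinal stem cell. That median was -0.01 with the block, which gives the same differences as leaving out RTC 2, and -0.03 without derivative #45. For primitive streak and mesoderm it was -0.00 with no filter. In RTCs against ESCs the median changed sign for interferon response with no filter (-0.01) and primitive endoderm without RTC 2 (-0.02). The causes were not tested, except that a filter at percentile 70 or a fold threshold changes how many genes can pass.

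With the filter at percentile 70, counts of genes were 469 for RTCs against ESCs, 92 for RTCs against derivatives, 697 for Apc Min/Min ESCs, 155 for organoids, 188 for S33 ESCs and 464 for S33 MEFs, and lists called were 7 in each of the first 2. As deposited, they were 358, 81 and 11 for RTCs against ESCs, RTCs against derivatives and derivatives against ESCs, and 726 for organoids. With all 18 arrays in the fit, 561 genes were called for RTCs against derivatives and 106 for derivatives against ESCs. At a fold of 1.5 and of 3, counts were 3219 and 320 in Apc Min/Min ESCs, 1346 and 85 in organoids, 1113 and 85 in S33 ESCs, and 1743 and 222 in S33 MEFs. Requiring 2-fold as well left 361 genes for RTCs against ESCs, Apc Min/+ as the sole ESC array gave 108 (92 of them shared), and leaving out fibroblast-high genes gave 231 in S33 ESCs. A replicate block gave 148 genes in MEFs and 8 lists for RTCs against derivatives.

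With an estimated correlation, 0 lists were called in all 4 tested comparisons (camera), against 13, 14, 4 and 10 with the preset one. Leaving out 1 array gave 234 to 1170 genes for RTCs against ESCs and 33 to 383 for RTCs against derivatives; where an arm was left with 1 array, that array was taken to vary like the others. Lists then called were 8 to 14 for RTCs against derivatives, 7 to 10 in MEFs and 6 to 12 for derivatives against ESCs. The correlation of RTCs minus derivatives with Apc Min/Min minus Apc +/+ was 0.14 to 0.45, and that of RTC with ESC arrays was 0.892 over the 1000 most variable genes.

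Of 431 values of named genes in RTCs against ESCs with an array left out, 303 kept their side of the threshold and 128 lost it. Of 215 in RTCs against derivatives, 146 kept it and 65 lost it, while 4 values of genes not past the threshold changed sign. Centring arrays on their median leaves correlations between arrays identical and was not run again for them.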

Other observations

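The tests in this part were all chosen after the results were seen, as was the germline list of 22 genes. Some germ cell genes outside the fixed lists were higher in contrasts of pluripotent cells that share controls, since Apc +/+ and S33 ESCs without dox are 2 of the 3 ESC arrays set against RTCs. Dazl, an RNA-binding protein of germ cells, was 2.71 ± 0.34 higher in RTCs than in ESCs (adjusted p = 0.00585), 2.82 higher in Apc Min/Min than in Apc +/+ ESCs and 2.16 higher in S33 ESCs with dox, with 1.18 ± 0.31 in RTCs against derivatives (adjusted p = 0.138). The piRNA pathway gene Mael rose by 1.24 ± 0.14 in RTCs against ESCs (adjusted p = 0.00388) and was at -0.72 in Apc Min/Min ESCs, and Ddx4 was at -0.24 ± 0.25 in RTCs (adjusted p = 0.609).

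A hypothesis was that such genes move together in these contrasts. In Apc Min/Min ESCs, 4 of 14 germline genes were at least 2-fold higher (median 0.56, percentile 99.92 among random lists), and in S33 ESCs with dox 2 of 11 were (median 0.55, percentile 99.99). The list was written after germ cell genes such as Dazl had been seen higher on these arrays. These percentiles may in part repeat that observation and do not test it. In RTCs against derivatives the list was not called by limma's camera test (median -0.11 of 14 measured, p = 0.642 with the preset correlation and 0.655 with an estimated one). Against the same 3 ESC arrays, so that a low level in these would raise both, the list was higher in RTCs (8 of 14 genes called, median 1.06, camera p = 1.33e-09, 0.0237 with an estimated correlation) and in derivatives (0 of 12 called by limma, median 0.90, camera p = 3.38e-11, 0.00676 with an estimated correlation). In RTCs against derivatives 5 of 14 were higher in value and 1 was called higher by limma, so whether the 2 differ in these genes stays open.

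Sterol synthesis genes were higher in RTCs against ESCs (16 of 20 in value, 3 of them called by limma, median 0.27, camera p = 0.000491, 0.103 with an estimated correlation) and, against the same ESC arrays, in derivatives (0 of 20 called, median 0.20, camera p = 0.00811, 0.164 with an estimated correlation). They were close to unchanged in S33 ESCs with dox (median 0.04 of 20 genes, percentile 75.5) and lower in Apc Min/Min ESCs (median -0.34, percentile 1.65).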
